A study of Mus musculus with 2 samples.

How the data were processed

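RNA of liver nonparenchymal cells was counted per cell in 2 droplet libraries of C57BL/6 mice, wild type and yap1, each a sample from 3 mice per the labels and each taken after 4 doses of carbon tetrachloride. The deposited files give, per the file headers, whole-number counts per gene and cell barcode, with Ensembl gene IDs and symbols. The counts behave as UMI counts and were not normalized. Per the submitters' processing notes the genome build was mm10 and the tools Bowtie 0.12.2 and Seurat, with no role given for either. The counting program, its annotation, its use of strand, the droplet chemistry and the rule by which barcodes were selected are not stated. Of 27998 gene IDs, 27645 were found in GENCODE M21, from which coordinates were taken, and 121 shared a symbol with another. Values per mouse are not analysed here.

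Barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs passed the filters: 4847 of 5269 wild-type and 4149 of 4731 yap1 barcodes. The automatic doublet threshold of Scrublet marked 0.268% and 0.241% of these, below the 0.5% under which it was taken not to have worked. The 4% of barcodes with the highest doublet scores were therefore left out in each library, 194 and 166. That step removed every wild-type basophil or mast cell-like cell, and that class, with 14 yap1 cells, was too small to be compared. The kept cells had median depths of 4073 and 5297 UMIs.

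Both libraries were clustered together without integration with scanpy 1.11.5, from counts scaled to 10000 and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Yap1, Lyz2 and mitochondrial, ribosomal, hemoglobin, sex-linked, immunoglobulin variable, hepatocyte and stress genes were kept out of the variable genes. Each cluster was named from 23 fixed marker lists, by the list with the highest score. It was called X-like where at least 3 markers were found in 25% of its cells and at 2-fold the level of the others. In addition, a marker of that list had to be among the cluster's 10 leading genes, and no other list could have more there. Clusters 13, 14 and 24 stayed unnamed. Clusters were defined by the same counts that are then compared, so genes among the 10 leading genes of a cluster are not reported as results of its class, except Lyz2, which carries Cre and leads a monocyte-like cluster.

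Per class and library, UMIs were summed and given as CPM with exact Poisson intervals. Ratios of yap1 over wild type carry exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95%. These cover counting error only, since neither mice nor libraries are replicated, and no test or p-value is given. A count of 0 is read as allowing up to 3 counts. For 27 gene lists the median log2 ratio over members with at least 20 UMIs is given, with an interval from 1000 Poisson resamples and its percentile among 10000 random lists of the same size matched in 10 bins of expression. These percentiles describe these libraries. Classes with at least 50 cells in each library were compared, 11 in all. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

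The lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are Yap1, Wwtr1, Lyz2, Ctgf, Cyr61, Vcam1 and Drd2, then up to 3 members of each list with the largest log2 ratio and at least 50 UMIs. To these are added, in the 4 main classes, the 8 highest and 8 lowest genes with at least 200 UMIs by the interval bound nearest to 1, and in other classes 3 and 3. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, sex-linked, hepatocyte and predicted genes were left out of that ranking. Genes beyond 1.5-fold the same way in every class are named up to 5 per direction. Some genes that this rule names, and 1 list that rests on such a gene, are not reported here. For each gene, the percent of 50-base words in the last 500 bases of its transcripts that also occur in another gene was computed.

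Alternatives kept doublets, used a stricter filter (1000 UMIs, 500 genes, 10% mitochondrial) or none, changed the resolution to 0.5 or 2, centred genes within each library, or left list genes out of clustering. For CPM ratios and medians they also scaled by the median of ratios or by a restricted total, weighted cells equally, thinned cells to 1000 UMIs, or required 100 UMIs per member. Single clusters, the class without cluster 15, the class without the 5 cells with most Ctgf and lists without genes that differ in every class were added after seeing the data.

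The calculations were tested on simulated counts with 200 changed genes. Class sums were drawn as independent Poisson counts, so the uneven spread of UMIs over cells was not simulated. The coverage below does not extend to it. For monocyte-derived macrophage-like cells (10310 genes), 95.2% of the intervals covered the true ratio, and the interval excluded 1 for 89.9% of 2-fold and 72.6% of 1.5-fold changes, against 4.73% of unchanged genes. For sinusoidal endothelial-like cells (8748 genes) these were 96.2%, 75.5%, 57.7% and 4.17%. In each of the 2 simulations 16 of 16 ranked genes were truly changed. In the first, 4 of 25 lists without an imposed change lay outside the central 95% of random lists, and 1 of 19 after lists that share genes with the changed list were left out; that exclusion was made after seeing the first count. In the second these were 0 of 25 and 0 of 19.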

Results

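Droplet-based single-cell RNA counts were analysed from liver nonparenchymal cells, the cells that stay in suspension after hepatocytes are pelleted. The cells came from C57BL/6 mice given carbon tetrachloride 4 times, a toxin that injures hepatocytes and is used to bring about liver fibrosis. A wild-type library was compared with a library from mice whose floxed Yap1 alleles are recombined by Cre from the Lyz2 locus, which is active in myeloid cells. Yap1 encodes a transcriptional coactivator of the Hippo pathway. The study's title concerns the dopamine receptor Drd2 and crosstalk between macrophages and endothelial cells in fibrosis, so myeloid and endothelial cells were compared first. The wild-type library held 5269 barcodes with 30386545 UMIs (median 3860 per barcode), and the yap1 library 4731 barcodes with 34234353 UMIs (median 4707). After filtering, 4653 and 3983 cells remained. Each genotype had 1 library, per the labels a sample from 3 mice, so no difference below has a replicate check or a test. All values compare these 2 libraries, and all intervals are 95% intervals that cover counting error only. Ratios are yap1 over wild type.

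The targeted gene and the Cre locus were examined first. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004596, mm10) was close to absent from myeloid cells of both libraries. Monocyte-derived macrophage-like cells held 2 Yap1 UMIs in the wild-type library and 3 in the yap1 library, a ratio of 0.848 (0.0972 to 10.2). Kupffer cell-like cells held 0 and 1, and monocyte-like cells 0 and 0, which allows up to 0.876 and 0.769 CPM (UMIs scaled by the class total). In sinusoidal endothelial cell-like cells, Yap1 stood at 67.9 CPM (55.6 to 82.1) and 67.9 CPM (52.9 to 86.0). Which part of Yap1 is floxed is not given in the sources used here, so these reads check neither the deletion nor the labels. Lyz2 (chromosome 10, 117277331 to 117282321), the lysozyme gene whose locus carries Cre, was lower in the yap1 library. Its ratio was 0.509 (0.504 to 0.514) in monocyte-derived macrophage-like cells, with 14330 and 7297 CPM. It was 0.541 in monocyte-like, 0.410 in Kupffer cell-like and 0.418 in neutrophil-like cells. In sinusoidal endothelial-like cells, outside the myeloid lineage, Lyz2 stood at 148.6 and 60.0 CPM, a ratio of 0.404 (0.2997 to 0.538). Cre at Lyz2 and the Yap1 deletion come together in the yap1 library, so their parts in the Lyz2 values of the myeloid classes cannot be told apart. The source of the Lyz2 UMIs in sinusoidal endothelial-like cells was not tested. Drd2 had 0 UMIs in each of these myeloid classes other than neutrophils and in sinusoidal endothelial-like cells, where 0 counts allow up to 1.92 and 2.95 CPM.

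The yap1 library held a larger share of monocyte-derived macrophage-like cells and a smaller share of Kupffer cell-like cells, the resident macrophages of the liver. Monocyte-derived macrophage-like cells made up 10.04% (9.19 to 10.9%) of wild-type and 16.9% (15.8 to 18.1%) of yap1 cells, a ratio of 1.69 (1.498 to 1.90). Kupffer cell-like cells made up 9.20% (8.38 to 10.1%) and 5.15% (4.48 to 5.88%), a ratio of 0.560 (0.471 to 0.662). By cluster, that ratio was 0.398 in cluster 6, 0.842 in cluster 15 and 0.653 in cluster 22. Monocyte-like shares were close, at 7.74% and 7.98%, and neutrophil-like cells stood at 9.005% and 12.03%. Sinusoidal endothelial-like cells stood at 9.86% (9.02 to 10.8%) and 8.31% (7.47 to 9.21%). B cell-like cells were the largest class, with 27.7% and 23.1%, and T cell-like cells stood at 7.63% and 8.59%. Plasmacytoid dendritic-like cells were fewer in the yap1 library, at 2.75% and 1.93%, as were plasma-like cells, at 25 and 5 cells, a ratio of 0.234 that was 0.704 when list genes were left out of clustering. Conventional dendritic cell 2-like, NK cell or ILC1-like and hepatocyte-like shares had ratios of 1.002, 0.987 and 1.07. The sinusoidal endothelial-like ratio of 0.842 was 0.7045 under the stricter filter. Kupffer cell-like cells had median depths of 2130 and 2836 UMIs, against 13158 and 15719 in monocyte-derived macrophage-like cells. The filters removed 8.01% of wild-type and 12.3% of yap1 barcodes.

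**Figure D1:**
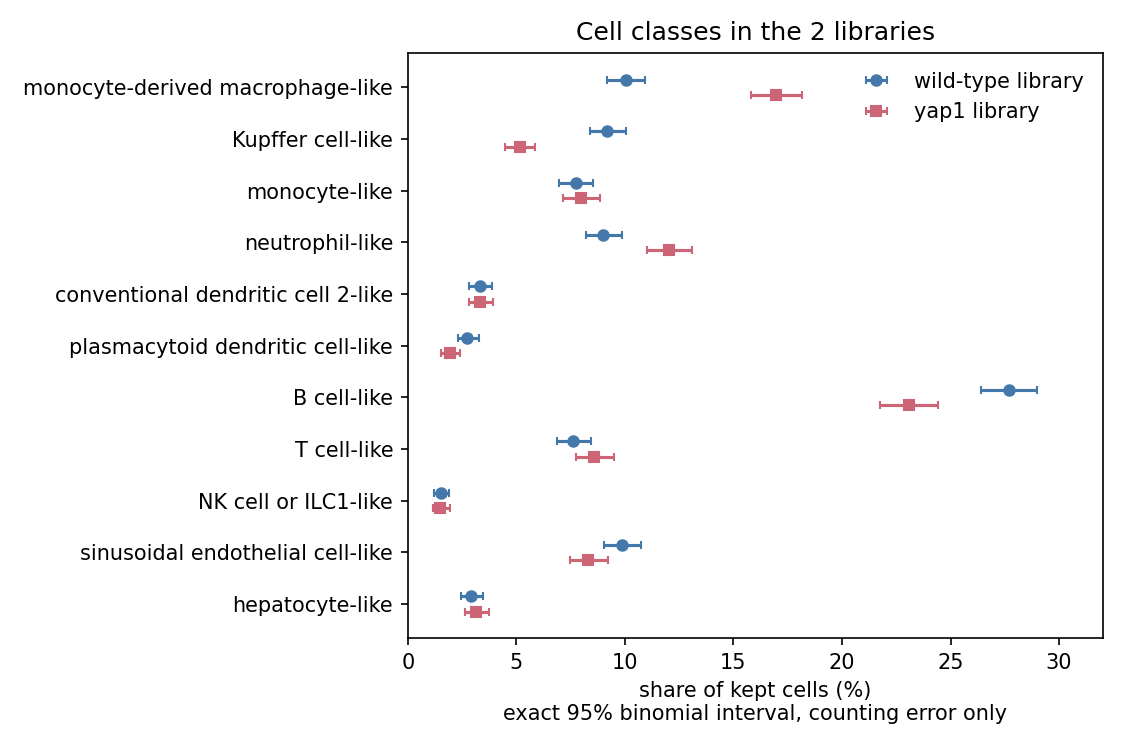
Share of kept cells in each class (x axis, %) in the wild-type library (circles) and the yap1 library (squares), with exact binomial 95% intervals that cover counting error only. Monocyte-derived macrophage-like cells stood at 10.04% and 16.9%, and Kupffer cell-like cells at 9.20% and 5.15%.

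In monocyte-derived macrophage-like cells (467 wild-type and 675 yap1 cells), transcripts of inflammatory cytokines and chemokines were lower in the yap1 library. Of 24 measured members of that list, 21 were lower and 3 higher. The median log2 ratio was -0.50 (-0.58 to -0.42), below the medians of all 10000 random lists matched on expression. Cxcl3 and Cxcl1, chemokines that attract neutrophils, had ratios of 0.293 (0.242 to 0.354) and 0.430 (0.401 to 0.462). The cytokines Tnf and Il1a had ratios of 0.471 (0.406 to 0.547) and 0.4996 (0.417 to 0.598), Tnf at 64.3 and 30.3 CPM. The 3 higher members were the interferon-induced chemokines Cxcl9 and Cxcl10, with ratios of 2.17 (43.2 and 93.9 CPM) and 1.34 (1.20 to 1.49), and Ccl2, at 1.005. Cxcl10 was 0.703 with each cell thinned to 1000 UMIs. Ccl2 was named after its value was seen.

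The repair and scar-associated list had 13 of 27 members higher in these cells, a median of -0.03 (-0.14 to 0.09) and percentile 22.7, though 0.14 in cluster 1 alone. The list shares members such as Gpnmb and Trem2 with the markers that name this class, so its median is not independent of that naming. Of its members beyond 1.5-fold, 8 were lower and 1 higher. Within it Il10, an anti-inflammatory cytokine, had a ratio of 0.351 (0.304 to 0.404) and the collagenase Mmp13 a ratio of 0.566 (0.360 to 0.889). Macrophage ligands with endothelial receptors had a median of -0.07 (8 of 20 higher), with Hbegf, an EGF receptor ligand, at 0.414 (0.249 to 0.679). YAP/TEAD target genes had a median of -0.16 (-0.31 to -0.05, percentile 4.5), with 8 of 9 members lower. Gadd45b stood at 0.679 and Nuak2 at 0.874, and Myof, named after its value was seen, was the higher member at 1.04. That median was -0.55 under the stricter cell filter. Ctgf and Cyr61, the best known YAP targets, had 1 and 11 UMIs and 2 and 0 UMIs here. Hippo pathway components had a median of -0.12 (1 of 9 higher), with Mob1b at 0.868.

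Complement and phagocytosis genes were lower in these cells, with 14 of 19 members lower and a median of -0.20 (-0.24 to -0.13, percentile 0.09). The phagocytic receptors Vsig4 and Marco stood at 0.261 and 0.448 and the scavenger protein Cd5l at 0.401. Iron and heme genes were lower as well, with 11 of 13 members lower and a median of -0.24 (-0.30 to -0.18, percentile 0.19). The iron exporter Slc40a1 had a ratio of 0.517. These 4 genes are also among the Kupffer cell markers, and the Kupffer cell-like share was lower in the yap1 library. Immediate early genes had a median of -0.14 (11 of 16 lower), with Socs3 at 0.591 and Egr1 at 0.622. Heat shock genes had a median of -0.26 (9 of 11 lower), and the small heat shock gene Hspb1 had 230 and 17 UMIs, a ratio of 0.0418 (0.0239 to 0.0684), or 0.202 under the stricter filter. Free hepatocyte RNA was lower in these cells, with 20 of 21 genes lower and a median of -0.96. All 4 hemoglobin genes were higher, at a median of 5.47, with 97.2% of the Hbb-bs UMIs of the yap1 cells in 5 cells, and the stricter filter gave -3.40.

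Neutrophil activation genes, which share members with the inflammatory list, had a median of -0.56 (-0.74 to -0.45, 16 of 18 lower), and the endothelial adhesion and inflammatory activation list a median of -0.43 (-0.56 to -0.26, 11 of 14 lower). The fibrillar matrix list stood at -0.35 (-0.59 to -0.08), but at 0.05 in cluster 1 alone, the shear stress list at -0.22 (-0.40 to -0.02) and T and NK effector genes at -0.29 (-0.38 to -0.16). Further medians were 0.02 for interferon-stimulated genes, -0.15 for MHC class II genes, 0.05 for lipid genes, 0.02 for glycolysis and hypoxia genes, 0.08 for cell cycle genes and -0.08 for sex-linked genes. Among single genes ranked by the bound nearest to 1, Lyz1, the lysozyme gene beside Lyz2, was the highest, with 28.4 and 349.0 CPM and a ratio of 12.3 (10.6 to 14.4). Gatm, which encodes the first enzyme of creatine synthesis, had a ratio of 2.82 (2.58 to 3.09), and the monocyte chemokine gene Ccl8 a ratio of 0.183 (0.141 to 0.236). The glycolytic gene Eno1 stood at 1.99, Lsm7 at 2.41 and Adap2os, an antisense transcript whose reads may not be separable from the opposite strand, at 0.184. For several ranked genes, most 50-base words at the 3' end also occur in another gene, so their counts are uncertain: Nme2 (0.125, 98.9% of words), Dynlt1f (2.32, 82.0%), Hmga1 (4.21, 69.4%) and Rab4b (0.187, 58.1%). For Dbndd2 (0.169) that part was 44.3%, and for Eno1 38.8%.

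**Figure D2:**
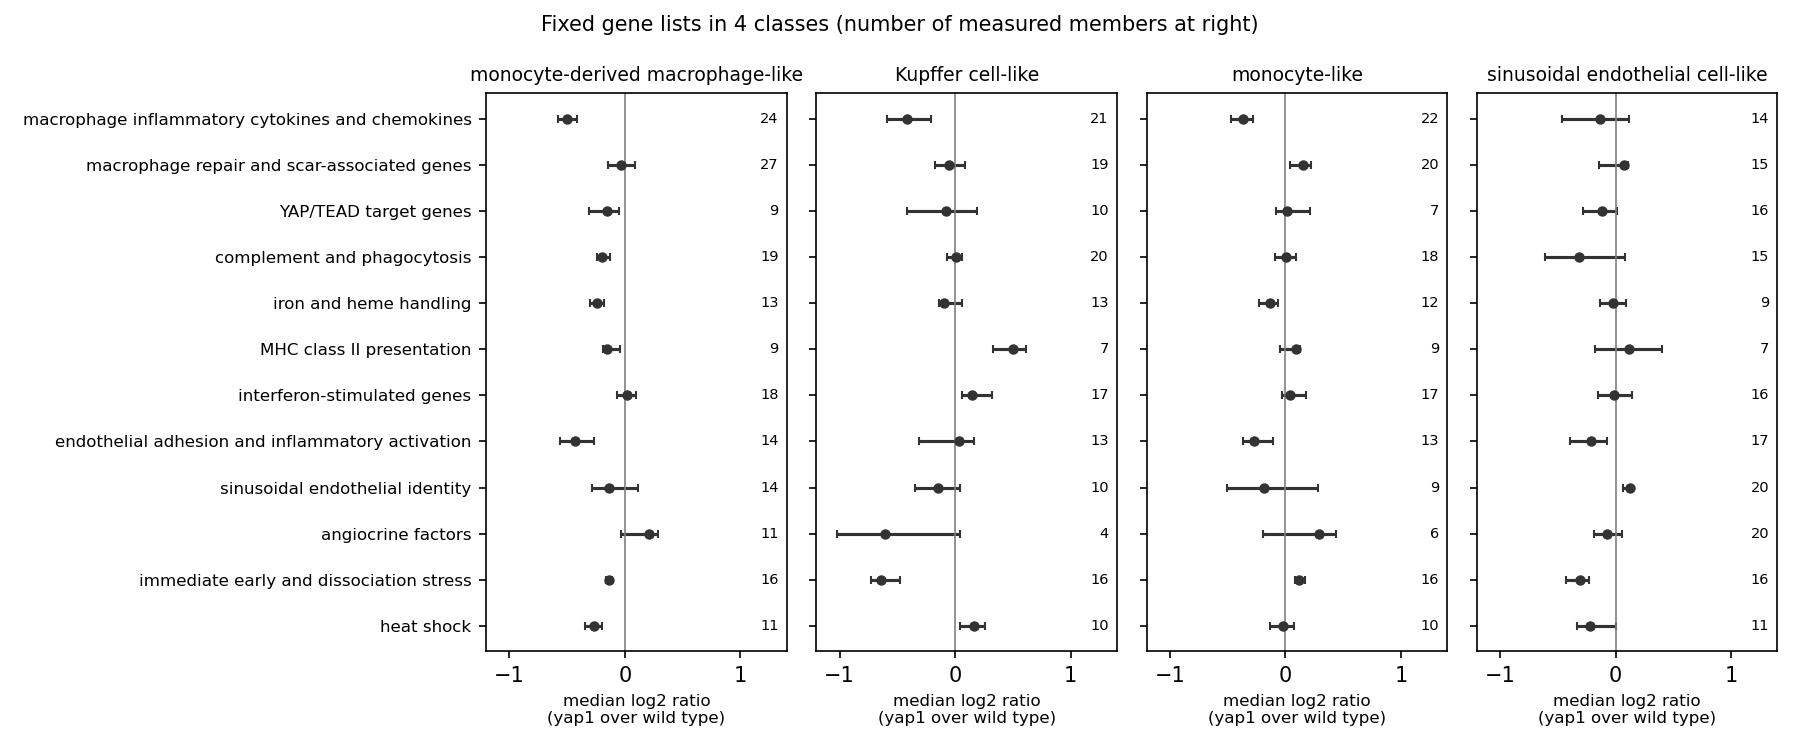
Median log2 ratio (x axis, yap1 over wild type) of 12 fixed gene lists (y axis) in 4 cell classes, with 95% intervals from Poisson resampling that cover counting error only and the number of measured members at the right of each panel. The macrophage inflammatory list lay at -0.50 in monocyte-derived macrophage-like, -0.42 in Kupffer cell-like and -0.36 in monocyte-like cells, and the MHC class II list at 0.50 in Kupffer cell-like cells.

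Kupffer cell-like cells (428 and 205) showed lower inflammatory and immediate early transcripts and higher MHC class II transcripts in the yap1 library. Most wild-type cells of this class lay in cluster 6 (60.3%), while the yap1 cells lay in clusters 15 (47.8%) and 6 (42.9%). The leading genes of cluster 15 include the cell cycle gene Cdk1, so the 2 libraries differ in their mix of these cells. The inflammatory list had a median of -0.42 (-0.59 to -0.21, percentile 0), with 14 of 21 members lower. Ccl3 had a ratio of 0.289 (0.203 to 0.403) and Il1b of 0.368 (0.314 to 0.430), though Il1b stood at 0.617 with cells weighted equally and 0.698 after thinning. Against that list's direction, the chemokine gene Ccl24 was higher, at 2.85 (2.39 to 3.42). Immediate early genes had a median of -0.64 (-0.73 to -0.48), with 15 of 16 lower, and -0.28 after thinning. All 7 measured MHC class II genes were higher, with a median of 0.50 (0.32 to 0.61, percentile 100), or 0.27 with doublets kept. Their invariant chain gene Cd74 had a ratio of 1.58 (1.45 to 1.73). Interferon-stimulated genes had a median of 0.15 (0.06 to 0.32), with 15 of 17 higher. A lower member was Cxcl10, at 0.384 (0.246 to 0.582), but at 1.70 with cells weighted equally.

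Among single genes of Kupffer cell-like cells, Gatm was again higher, at 2.18 (1.96 to 2.43), as were the sodium pump subunit gene Atp1b3 at 1.90 and the matrix protein gene Tgfbi at 1.91. Pla2g7, which encodes a phospholipase that degrades platelet-activating factor, was lower, at 0.242 (0.167 to 0.342). Il10 stood at 0.310, but at 0.719 with cells weighted equally, and the elastase gene Mmp12 at 0.348, or 0.619 under the stricter filter. The heme oxygenase gene Hmox1 had a ratio of 0.623 (0.571 to 0.678). YAP/TEAD targets had a median of -0.08 (-0.41 to 0.19), or 0.28 after thinning, the repair list -0.06, the complement list 0.01 and the iron list -0.10. Heat shock genes had a median of 0.16 and free hepatocyte RNA of 0.28 (-0.02 to 0.59). Neutrophil activation genes, which share Il1b, Ccl3 and other members with the inflammatory list, had a median of -0.61, with 10 of 11 lower.

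Monocyte-like cells (360 and 318, clusters 3 and 11) also had lower inflammatory transcripts in the yap1 library. The list had a median of -0.36 (-0.47 to -0.28, percentile 0), with 17 of 22 members lower, and -0.21 when list genes were left out of clustering. Cxcl1 had a ratio of 0.189 (0.131 to 0.267), or 0.472 in that clustering, and Il1b stood at 2434 and 1533 CPM, a ratio of 0.630 (0.609 to 0.651). Immediate early genes lay on the other side of 0, with a median of 0.11 (0.08 to 0.17), 11 of 16 higher and Fos at 1.46 (1.39 to 1.52), but Egr1 at 0.609 (0.498 to 0.744). The repair list was higher, with a median of 0.15 (0.04 to 0.22), but 0.01 with doublets kept. Glycolysis and hypoxia genes had a median of 0.13 (-0.01 to 0.28) and YAP/TEAD targets of 0.02. Lyz1 had 14 UMIs in wild-type and 1278 in yap1 cells, a ratio of 80.2 (47.6 to 147), or 24.6 with doublets kept. Of the 318 yap1 cells, 3 held 50% of these UMIs, and 84.6% (79.5 to 89.0%) of those with at least 50 Lyz2 UMIs had 0 Lyz1 UMIs. Gatm stood at 4.23 and S100a9, a calcium-binding alarmin gene of neutrophils and monocytes, at 2.18 (1.94 to 2.46). The acute phase gene Saa3 had a ratio of 0.162 (0.145 to 0.181) and the Kupffer cell marker Marco a ratio of 0.0959 (0.0496 to 0.170), which thinning moved to 0.2496.

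Sinusoidal endothelial-like cells (459 and 331, clusters 2 and 8) were the other side of the crosstalk named in the title. Their adhesion and inflammatory activation genes were lower in the yap1 library, with 11 of 17 lower and a median of -0.21 (-0.39 to -0.07, percentile 0.44). Immediate early genes, given below, were lower in these cells too, and handling was not tested as a cause of the adhesion values. In these cells Lyz2 stood at 0.404 and Plac8 at 0.417 (0.313 to 0.550), while Cd74 stood at 1.31 (1.10 to 1.56). The complement and phagocytosis list had a median of -0.32 (-0.61 to 0.08, 9 of 15 lower) and the neutrophil activation list of 0.14 (-0.19 to 0.39, 7 of 11 higher). Vcam1 (chromosome 3, 116109949 to 116129688), which encodes an adhesion receptor for leukocytes, stood at 283.1 CPM (257.3 to 310.8) and 155.5 CPM (132.2 to 181.8). Its ratio of 0.549 (0.455 to 0.660) lay between 0.461 and 0.579 under the 9 alternatives. The chemokine gene Cxcl10 had a ratio of 0.514 (0.418 to 0.628), or 0.773 after thinning. Ackr1, a chemokine-binding receptor of venules, went the other way, at 1.82 (1.35 to 2.44). Yap1 acts through transcription factors whose targets include Ctgf (chromosome 10, 24595442 to 24598683). Ctgf stood at 470.8 CPM (437.4 to 506.1) and 450.9 CPM (410.5 to 494.1), a ratio of 0.958 (0.850 to 1.08). That value rested on a few cells: without the 5 cells of each library with most Ctgf UMIs the ratio was 0.502, with cells weighted equally 0.522, and under the stricter filter 1.29.

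The share of sinusoidal endothelial-like cells with a Ctgf or Vcam1 UMI was lower in the yap1 library. For Ctgf it was 24.2% (20.3 to 28.4%) and 13.6% (10.1 to 17.8%), and for Vcam1 30.9% (26.7 to 35.4%) and 19.6% (15.5 to 24.3%). Cells with a UMI of both made up 10.2% (7.62 to 13.4%) and 5.14% (3.02 to 8.10%). After thinning each cell to 1000 UMIs, which left out 101 and 72 cells, the shares were 17.9% (14.0 to 22.2%) and 11.6% (7.95 to 16.1%) for Ctgf, and 15.6% (12.04 to 19.8%) and 11.6% (7.95 to 16.1%) for Vcam1. For both genes together they were 4.47% (2.58 to 7.16%) and 2.70% (1.09 to 5.49%). The intervals of the libraries overlap for each of these. Thinned to 500 UMIs, which left out 0 cells, the shares were 12.4% (9.54 to 15.8%) and 5.74% (3.49 to 8.82%) for Ctgf and 8.71% (6.30 to 11.7%) and 3.32% (1.67 to 5.87%) for Vcam1, whose intervals do not overlap, and 1.31% (0.481 to 2.82%) and 0.604% (0.0733 to 2.17%) for both genes together. In B cell-like cells, which should lack both genes, 0.155% and 0.218% of cells had a Ctgf UMI and 0.932% and 0.762% a Vcam1 UMI. Before thinning, 48.1% and 51.2% of Kupffer cell-like cells had a Vcam1 UMI, and their share was lower in the yap1 library. Free RNA from them would reach B cell-like cells too. The low Vcam1 shares there, at greater depth, argue against free RNA as the source of most endothelial Vcam1 UMIs. B cell-like cells are no check for Kupffer cells joined to endothelial cells, whose part in the endothelial Vcam1 values was not tested. Median depths were 2220 and 2189 UMIs in the endothelial class and 3652 and 4411 in B cell-like cells.

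YAP/TEAD targets as a list had a median of -0.12 (-0.28 to 0.01, percentile 18.3) in sinusoidal endothelial-like cells, with 10 of 16 lower. Cyr61, a matrix protein gene, stood at 0.619 (0.394 to 0.9502), and at 0.238 without the 5 cells with most Ctgf. Wwtr1, the Yap1 paralogue, stood at 0.868 (0.731 to 1.03), and Hippo pathway components had a median of 0.06. Angiocrine factors had a median of -0.08 (-0.19 to 0.06), with 11 of 20 lower. Rspo3, which amplifies Wnt signals to hepatocytes, had a ratio of 0.627 (0.532 to 0.738), the Notch ligand gene Jag1 of 0.399 (0.204 to 0.727) and Angpt2 of 0.561 (0.332 to 0.917). Receptors for macrophage ligands had a median of 0.00 with 11 of 21 higher, with the chemokine receptor gene Cxcr4 at 2.31 (1.37 to 3.94), or 1.10 with doublets kept, and the oncostatin M receptor gene Osmr at 0.666 (0.513 to 0.860). Shear stress and quiescence genes had a median of -0.16 (-0.29 to -0.09), or -0.03 with doublets kept, and the anticoagulant receptor gene Thbd stood at 0.695 (0.597 to 0.808). Capillarization and basement membrane genes had a median of -0.05, and Esm1, an endothelial proteoglycan gene, stood at 1.76 (1.47 to 2.11). Fibrillar matrix genes had a median of -0.26 over 7 members.

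The retinoic acid-degrading enzyme gene Cyp26b1 (chromosome 6, 84571414 to 84593908) had the highest ratio of the genes with at least 200 UMIs in sinusoidal endothelial-like cells. It stood at 189.6 CPM (168.6 to 212.5) and 1027 CPM (965 to 1091), a ratio of 5.42 (4.76 to 6.18). Dhrs3, another retinoid enzyme gene, had a ratio of 1.68 (1.47 to 1.92), Gchfr, a regulator of tetrahydrobiopterin synthesis, of 2.21 (1.66 to 2.97). The sinusoidal identity list, which shares most members with the markers that name the class, had a median of 0.12 (0.07 to 0.14), with its members Gata4, a transcription factor gene, at 1.37 (1.15 to 1.64) and Il1a at 1.78 (1.44 to 2.20). Lower genes included the cytokine signalling inhibitor Socs3 at 0.463 (0.394 to 0.542) and the protease inhibitor gene Cst3 at 0.501 (0.446 to 0.562). Immediate early genes had a median of -0.31 (-0.43 to -0.23), with 14 of 16 lower, but -0.02 with doublets kept. Heat shock genes had a median of -0.22 (-0.34 to 0.00). T and NK effector genes lay at a median of 1.91 over 5 members, with Ccl5, at 16 and 39 UMIs, the middle member (3.75, 2.05 to 7.18). The Ccl5 ratio was 0.269 with doublets kept and 0.362 under the stricter filter.

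**Figure D3:**
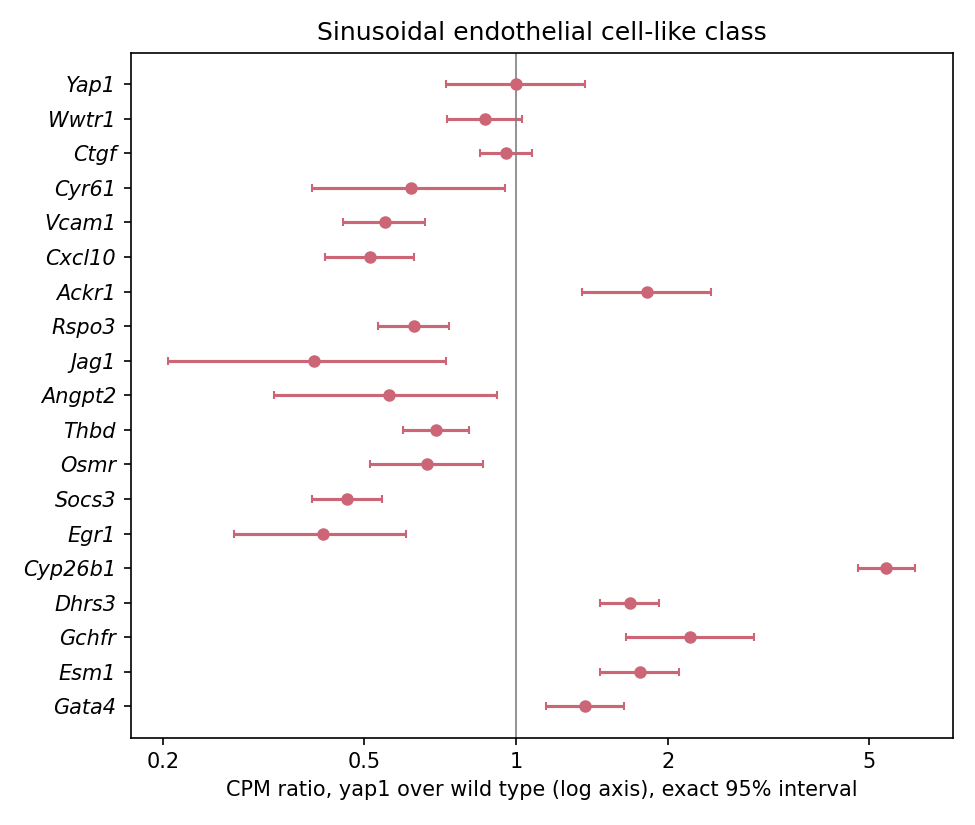
CPM ratio (x axis, log scale, yap1 over wild type) of 19 named genes in sinusoidal endothelial cell-like cells, with exact 95% intervals that cover counting error only. Vcam1 lay at 0.549, Ctgf at 0.958 and Cyp26b1 at 5.42.

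Classes outside these comparisons differed as well, but their gene ratios and list medians were not recomputed under any alternative. In plasmacytoid dendritic-like cells, 13 of 13 measured interferon-stimulated genes were lower in the yap1 library, with a median of -0.95 (-1.27 to -0.45). Complement and phagocytosis genes, which are macrophage transcripts, were lower there too, with 5 of 6 lower and a median of -1.61 (-2.14 to -0.93). In conventional dendritic cell 2-like cells 16 of 18 interferon-stimulated genes were higher, with a median of 0.26 (0.13 to 0.40). Cxcl10 had 19 and 195 UMIs there, a ratio of 10.3 (6.40 to 17.4). Apoe was lower there, at 0.143 (0.129 to 0.159), and 7 of 8 T and NK effector genes were higher, with a median of 0.61 (0.40 to 0.91). In neutrophil-like cells, where clusters 5 and 7 held 47.7% and 32.2% of the wild-type and 38.4% and 41.1% of the yap1 cells, all 16 immediate early genes were higher, with a median of 0.40 (0.35 to 0.45, percentile 99.8), while the median over all measured genes of that class was 0.21. The inflammatory list had 10 of 17 members higher in neutrophil-like cells, with a median of 0.11 (0.01 to 0.29, percentile 30.4), and 10 of 17 in conventional dendritic cell 2-like cells, with a median of 0.02 (-0.06 to 0.14). The metallothionein genes Mt1 and Mt2 were lower in hepatocyte-like cells, at 0.227 (0.204 to 0.253) and 0.214 (0.172 to 0.263), and Cd74 was higher there, at 10.9 (7.08 to 17.7). In B cell-like cells Fos had a ratio of 2.18 (1.99 to 2.39).

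Of 1856 genes measured in all 11 classes compared, 12 differed beyond 1.5-fold the same way in every class. Those higher in the yap1 library, 6 in number, were Rpl35, Rpl38, Rps29, Gm10076, Polr2l and Rps27. The 6 lower were Wdr89, Gm11808, Rps27rt, AY036118, Rnaset2b and Rnaset2a. Wdr89 had the lowest ratios, from 0.104 to 0.198 across classes. Rps27 and Rnaset2a lay outside the fixed number of named genes and were named after their values were seen. For 7 of the 12, over 50% of the 50-base words at the 3' end also occur in another gene, so the counts of those 7 are uncertain. That part was 27.1% for Rps27, 19.8% for Wdr89, 5.32% for Polr2l and 0% for Rpl38 and Rps29.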

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

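The tests of shared sequence, of the region around Lyz2 and of subclusters were set before their results were seen, and all other tests here were chosen after the result was seen. The test in fibroblast or myofibroblast-like and cholangiocyte-like cells replaced a first test in the classes that had been used to choose the genes, which could not have come out otherwise. Opposite directions between classes were picked by a rule set after the list medians were seen, and none of these differences between classes was tested.

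The cell cycle list had a median log2 ratio of 0.92 (0.9225) in hepatocyte-like and -1.76 (-1.759) in neutrophil-like cells, of which cluster 20, led by Camp, Ngp and Ltf, made up 10.3% in the wild-type and 4.38% in the yap1 library. The immediate early list stood at 0.45 (0.4478) in plasmacytoid dendritic-like and -0.64 (-0.6395) in Kupffer cell-like cells. Interferon-stimulated genes stood at 0.26 (0.256) in conventional dendritic cell 2-like and -0.95 (-0.9512) in plasmacytoid dendritic-like cells. The repair and scar-associated list stood at 0.15 (0.1546) in monocyte-like and -0.34 (-0.3398) in conventional dendritic cell 2-like cells. Barcodes that failed the filters, which enter only the alternative without filters, held Hbb-bs at 102942.809 CPM in the wild-type and 212385.038 CPM in the yap1 library, with 28 and 79 erythroid-like barcodes.

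Genes that differed beyond 1.5-fold the same way in all 11 classes numbered 6 higher and 6 lower. In fibroblast or myofibroblast-like and cholangiocyte-like cells (51 and 31), which took no part in choosing these genes, 12 of 12 went the same way, with a median log2 ratio in that direction of 1.22 (0.95 to 1.56), which argues against a Yap1 deletion acting within the Lyz2 lineage as the whole cause. A median of 68.67% of their 3' words occur in another gene, above the 2.755% that marks the top of random gene sets, so reads split differently between near-identical genes in the libraries may be the cause for the 7 with over 50%. Rps27 (27.1%), Wdr89 (19.8%), Polr2l (5.32%), Rpl38 (0%) and Rps29 (0%) share fewer words, and a difference between the library preparations stays open because each genotype has 1 library.

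Lyz1 was higher in monocyte-derived macrophage-like and monocyte-like cells of the yap1 library. Lyz2 reads counted as Lyz1 would leave 2.255% of cells with at least 50 Lyz2 UMIs without Lyz1, and 75.14% had none, which argues against it. Free Lyz1 RNA is argued against by a level 243.3 times that of T and B cell-like cells. A strain variant carried along with the Cre locus cannot be told apart from the genotype: 3.448% (0.087 to 17.8%) of 29 neighbouring genes lay beyond 1.5-fold, against 5.46% on the rest of the chromosome, which says nothing of Lyz1 itself. The Yap1 deletion, Cre at the Lyz2 locus and a difference between mice stay open and untested. Of 993 cells, 20 held 50% of the Lyz1 UMIs.

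The inflammatory list was lower in monocyte-derived macrophage-like, Kupffer cell-like and monocyte-like cells, but not in conventional dendritic cell 2-like cells (0.02). In neutrophil-like cells it stood at 0.11, below the median over all measured genes of that class. Among lymphoid classes, it was lower in NK cell or ILC1-like cells (-0.52, -0.62 to -0.14, 6 of 7 lower). It stood at 0.34 (-0.12 to 0.64) in T cell-like and -0.17 (-0.32 to 0.13) in B cell-like cells. In monocyte-like cells an immediate early median of 0.1147 argues against less handling response in the yap1 library. In monocyte-derived macrophage-like and Kupffer cell-like cells the immediate early list was lower too (higher value -0.1404), so handling and genotype cannot be told apart there. For monocyte-derived macrophage-like cells, free RNA is argued against by a fall in B cell-like cells of 1.391% of the gap; a first measure, the whole wild-type B cell-like level, gave 11.42%, between its set bounds, and was replaced after it was seen. Another mix of the 2 subclusters with at least 50 cells per library is argued against by a median of -0.5318 within them (-0.44 and -0.62). Smaller subclusters, and shifts between states inside these 2, were not tested. The genotype stays open and untested, as do differences between mice and preparations.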

How the results depend on the processing

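Of 98 alternative values of cell shares, 95 stayed within the counting interval. So did 1650 of 1967 for gene ratios and 793 of 926 for list medians. Where the main interval excluded 1 or 0, 16 alternative values of ratios and 6 of medians lay on the other side of it. Crossings from main intervals that include 1 or 0, such as that of sinusoidal endothelial-like Ctgf, are not in these counts. The inflammatory median of monocyte-derived macrophage-like cells stayed between -0.55 and -0.46, and the Vcam1 ratio of sinusoidal endothelial-like cells between 0.461 and 0.579. In the 4 main classes, scaling moved the median of all genes by less than 0.1 on the log2 scale. In the other classes, gene ratios and list medians were not recomputed under any alternative. The cause was not tested for any value below. No paired analysis was possible because each genotype has 1 library. For Lyz2 in monocyte-derived macrophage-like cells the ratio was 0.516 with doublets kept, 0.5242 without list genes in clustering, 0.5043 by median of ratios, 0.5227 by restricted total, 0.5147 with equal weights, 0.5184 thinned and 0.5185 in cluster 1. Without list genes, the Kupffer cell-like share ratio was 0.4386, the monocyte-like inflammatory median -0.2055, the macrophage matrix median 0.01479 (0.0456 in cluster 1), monocyte-like H2-Eb1 1.011 and its T and NK median 0.05979. Under the stricter filter, the endothelial share ratio was 0.7045, the macrophage YAP/TEAD median -0.5535, macrophage hemoglobin -3.404, Ctgf 1.291, monocyte-like H2-Eb1 1.366 and endothelial Ccl5 0.3625. With doublets kept, Ccl5 was 0.2688, Kupffer cell-like Egr1 1.407, and monocyte-like Axl 0.946, H2-Aa 0.883, Fosb 0.975 and Hspa1a 0.9039. With equal weights, Ctgf was 0.5217, the endothelial adhesion median -0.4606 (range over 10 alternatives -0.46 to -0.12), and Kupffer cell-like Cxcl10 1.695 and Ifit3 0.9741. Thinned to 1000 UMIs, Ctgf was 0.6103, macrophage Nuak2 1.218 and Cxcl10 0.7028, Kupffer cell-like H2-DMb1 0.8793, Fosb 1.187, inflammatory median -0.6479 and glycolysis median -0.05268, and monocyte-like Cxcl3 3.369 and adhesion median 0.01539. Ctgf was 1.155 in cluster 8 and 0.5021 without its 5 highest cells, and thinned to 500 UMIs the ratio of Vcam1-positive shares was 0.3813.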

Other observations

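Cluster 24, unnamed and led by interferon-induced genes, held 7 wild-type cells (0.1504%, 0.0605 to 0.310%) and 25 yap1 cells (0.628%, 0.407 to 0.925%). The interferon-stimulated medians of all classes leave these cells out, since the cluster entered no class. Hepatocyte-like cells of the yap1 library had more cell cycle transcripts, with 15 of 17 genes higher and the ubiquitin-conjugating enzyme gene Ube2c at 3.10 (2.31 to 4.21). This class had a median depth of 1463 UMIs and a median mitochondrial share of 0.529%. Over all kept cells that share was 4.45% in the wild-type and 4.05% in the yap1 library. Markers of other cell types were higher there too: 4 of 4 MHC class II genes, with a median of 2.96, and 4 of 4 hemoglobin genes, with a median of 7.26 and 99.6% of the Hbb-bs UMIs of the yap1 cells in 5 cells. In NK cell or ILC1-like cells 7 of 9 cell cycle genes were higher, with a median of 0.85 (0.37 to 1.24), the T cell marker Cd3g stood at 2.31 (1.79 to 3.01), and Gadd45b stood at 0.378 (0.292 to 0.487). In plasmacytoid dendritic-like cells the activation marker gene Cd69 had a ratio of 1.88 (1.55 to 2.28) and Jund of 1.65 (1.52 to 1.79), while the heat shock gene Hspa1b stood at 0.390 (0.274 to 0.547). In conventional dendritic cell 2-like cells 11 of 15 complement and phagocytosis genes were lower, with a median of -0.70 (-0.98 to -0.32). Neutrophil-like cells had the transglutaminase gene Tgm2 at 2.55 (2.19 to 2.98).

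Within 5 Mb of Yap1, 4 of 15 measured genes lay beyond 1.5-fold in monocyte-derived macrophage-like cells (26.7%, 7.79 to 55.1%), against 6.71% on the rest of chromosome 9. These were Casp4, Mmp8, Mmp12 and Mmp13, of which Casp4, Mmp8 and Mmp12 were chosen after their values were seen. The interval treats genes as independent, which neighbours such as Mmp13 and Mmp12 (starts at 7272514 and 7344381) may not be. Mmp12 is also among the markers that name this class.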
